A study of Mus musculus with 5 samples.

How the data were processed

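RNA was measured in 5 libraries of hepatocytes sorted from the livers of ICR mice, an outbred stock. Per the series' design text, the mice had been given a fluorescent probe of fatty acid oxidation (FAO), and cells were parted by fluorescence-activated cell sorting. Groups were taken from the labels. Negative and positive gates were taken from control mice. Negative, positive and high gates were taken from mice given bezafibrate, an agonist of peroxisome proliferator-activated receptors (PPARs). Each of the 5 groups has 1 library. The number of mice behind a library, the sex, the dose, the time of day and whether the gates of a treatment came from 1 liver are not given in the sources used here. Treatment is therefore confounded with mouse. Per the labels' protocols, total RNA was isolated with a kit named for fixed, embedded tissue, ribosomal RNA was depleted, and strand-specific libraries were sequenced as read pairs.

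The authors deposited 1 table of normalised gene-level signal for 13966 gene symbols. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2, RSEM and edgeR were used with genome build mm10; the notes give no roles, and the annotation is not given in the sources used here. The normalization is not given in the sources used here; from the values, the deposited signal is a read count divided by 1 factor per library. The 5 column totals lie between 910193 and 1119940. Dividing a column by its smallest value above 0 gave whole reads for 100% of values in each library, with a tolerance of 0.001 reads. The recovered totals were 5454866 reads for control negative, 5056884 for control positive, 7146578 for bezafibrate negative, 5993366 for bezafibrate positive and 6831281 for bezafibrate high. Every gene in the table had at least 5 reads summed over the libraries. Of the symbols, 95.8% matched 1 gene of the annotation used here.

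Genes were analysed when their mean over the 5 libraries reached a normalised read count of 5.02, and 8973 genes did. Values were compared as differences of log2(value + pseudocount), with a pseudocount of 1.0035 normalised read counts. Pseudocounts and filters are named below as multiples of this pseudocount, which makes the main settings 1 and 5. This scale understates differences of low genes. Fold values are plain ratios of the deposited values, with exact Clopper-Pearson 95% intervals from the recovered reads. A gene listed at 0 was given a floor of 3 reads in that library. Intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules.

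With 1 library per group there is no replicate check, and no p-value is given. Genes were counted at 2-fold or more. The number expected from counting alone came from 100 Poisson draws from the mean of the 2 libraries. For 38 gene lists fixed before the data were examined, of which 28 had at least 5 members among the genes analysed, the median log2 difference was placed among 10000 random lists of the same size matched on mean value in 20 bins. A list is said to stand apart below the percentile 2.5 or above 97.5; percentiles are rounded and describe these libraries only. The 10 lists without 5 members were those of other cell types, described by their summed values, and of mitochondrially encoded transcripts, of which 0 were in the table. Genes named in the text were the 10 with the largest positive and the 10 with the largest negative difference per comparison, without provisional names, pseudogenes, small RNAs and ribosomal RNA. The 2 most abundant and the 2 most extreme members of each list described, and 12 reference genes, were also named. Some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen, and the text says so.

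An additive fit of gate and treatment over 4 libraries was made with limma 3.58.1 in R 4.3.3, with a trended prior and Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, takes the gate by treatment difference as error and is not a test between replicates. On the recovered whole reads, edgeR 4.0.16 was run with the same design, an alternative chosen after the data were seen. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Coordinates and transcript lengths came from GENCODE for GRCm38, the assembly also called mm10.

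The steps were tested on simulated data. For control positive minus control negative, with 8951 genes, 2-fold calls took in 0% of genes simulated at 1.5-fold, 98% at 2.5-fold and 100% at 4-fold and 8-fold, and 0.0343% of unchanged genes. Of 200 random lists simulated without a difference, 5% stood apart, while 68% of lists shifted by 0.1 and 100% of lists shifted by 0.2 on the log2 scale did. These lists were random genes with independent counting error, so the limits themselves set the 5%. It does not give the rate for lists whose members vary together. For the simulated treatment term with 8973 genes, limma called 14% of genes at 1.5-fold, 86% at 2-fold and 100% at 4-fold. That simulation took the same fixed dispersion for all genes and no gate by treatment difference. Its shares may therefore not hold for the measured libraries. Alternatives tried were 3 other scalings (column totals, median of ratios and totals without the 100 highest genes), pseudocounts of 0.25 and 5, filters at 1 and 20 and no filter, the mean in place of the median and unmatched random lists. Matching on transcript length or RNA make-up, and the bezafibrate high library in place of the positive one, were added after the data were seen. RNA make-up was matched through a difference between 2 bezafibrate gates, beside the mean value, and not through a measured share. It was high minus positive for bezafibrate against control in the negative gate. For the positive gate and for the control gates it was high minus negative.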

Results

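Hepatocytes were sorted from mouse liver by the signal of a fluorescent probe of fatty acid oxidation, to describe how hepatocytes of differing FAO activity differ in their RNA. The 5 libraries are negative and positive gates of control mice, and negative, positive and high gates of mice given bezafibrate. Each group has 1 library, so no difference below has a replicate check and each describes these libraries, not the conditions. Recovered depth lay between 5056884 reads in control positive and 7146578 in bezafibrate negative. Values are normalised read counts as deposited, and differences are given on the log2(value + pseudocount) scale.

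The libraries differed in RNA make-up. Rn45s, the gene of the ribosomal RNA precursor, held 36.3% of reads in control negative (95% Clopper-Pearson interval 36.3 to 36.4) and 34.8% in control positive (34.7 to 34.8). It held 10.5% in bezafibrate negative, 18.5% in bezafibrate positive and 13.5% in bezafibrate high, with intervals that round to the same values. The nuclear RNA Malat1 (chromosome 19, 5795690 to 5802672) had normalised read counts of 23146 and 22835 in control negative and positive, and of 15406, 19155 and 17208 in bezafibrate negative, positive and high. Neat1, also a nuclear RNA, had 20162, 19968, 11978, 15385 and 14966 in the same order. Albumin RNA ran the other way, with 2.17% (2.16 to 2.18) and 2.12% of reads (2.10 to 2.13) in the control negative and positive libraries. It held 7.58% (7.56 to 7.60), 5.10% (5.09 to 5.12) and 5.99% (5.97 to 6.01) in bezafibrate negative, positive and high. A large Rn45s share lowers the share of every other gene. Of reads outside Rn45s, albumin held 3.41% and 3.24% in control negative and positive. The shares were 8.47%, 6.26% and 6.93% in bezafibrate negative, positive and high. Rn45s, Malat1 and Neat1 were chosen after their values were seen. Ribosomal RNA was depleted from these libraries, and how far that step set the Rn45s share was not measured. Whether Rn45s reads came from precursor or mature ribosomal RNA was not determined.

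**Figure D1:**
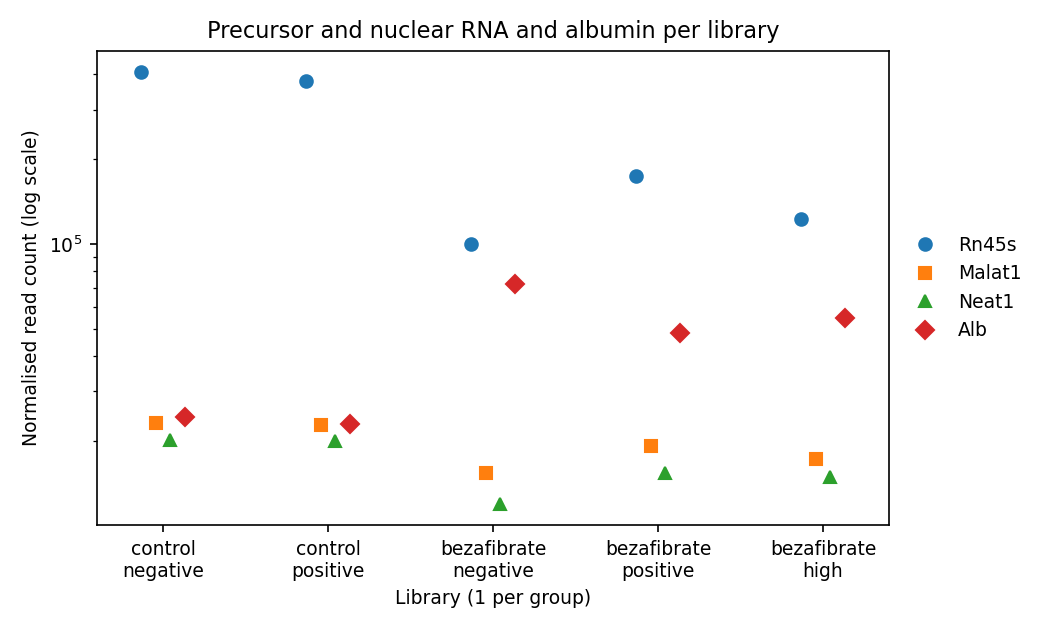
Normalised read counts (log axis) of Rn45s, Malat1, Neat1 and Alb in each of the 5 libraries, 1 point per gene and library, with no replicates and so no error bars. Rn45s sits at 407070 and 379099 in the control libraries and between 99961 and 174815 in the bezafibrate libraries.

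Markers of other liver cells were low. Summed over each list, in the order control negative, control positive, bezafibrate negative, bezafibrate positive and bezafibrate high, Kupffer cell and macrophage genes reached 79.0, 78.9, 149.7, 116.9 and 127.1. Sinusoidal endothelial genes reached 68.2, 52.6, 59.6, 68.1 and 84.2, and stellate cell genes 138.4, 140.6, 58.5, 55.8 and 77.0. Cholangiocyte genes reached 127.7, 123.1, 92.4, 100.1 and 107.0. The iron exporter Slc40a1 alone held 67.3 to 140.0 of the first list and Reln 28.5 to 105.8 of the third. These members were picked out after their values were seen. Lists of T and NK cells, B cells, neutrophils, erythroid cells and platelets each stayed at or below 46.5 in these libraries. Albumin, for scale, lay between 23064 and 72188.

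Between the gates of control mice, genes of pericentral hepatocytes, which surround the central vein, were higher in the positive library and genes of periportal hepatocytes were lower. The median of 36 pericentral genes was 0.20 higher, at percentile 100 among random lists, with 34 members above and 2 below 0. Glul, glutamine synthetase of the cells next to the central vein, was 1.36-fold higher (95% counting interval 1.20 to 1.53), and Cyp2e1 1.25-fold higher (1.20 to 1.31). Mup17 was 1.58-fold higher (1.34 to 1.87), though reads of the Mup genes cannot be assigned with certainty among near-identical copies, while Sult5a1 was lower at 37.9 against 51.3. The median of 41 periportal genes was -0.10, at percentile 0, with 33 members below 0. Sds, serine dehydratase, had 343.4 in the positive against 499.3 in the negative library, and Cyp2f2 762.1 against 903.0, while Spp2 had 19.8 against 16.2.

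Of the fatty acid oxidation lists, omega-oxidation stood apart between the control gates, and the mitochondrial and peroxisomal lists did not. The 25 genes of mitochondrial beta-oxidation had a median difference of -0.01 (percentile 29.7), with 12 members above and 13 below 0. Cpt1a, the carnitine palmitoyltransferase at the entry to that pathway, was 0.949-fold (0.885 to 1.02). The 29 peroxisomal genes had a median of 0.03 (percentile 80.2), and the 11 genes of omega-oxidation, the Cyp4 pathway in the endoplasmic reticulum, 0.13 (percentile 99.9). Ehhadh, of the peroxisomal list, was 1.20-fold higher in the positive library (1.04 to 1.39) and Cyp4a14 1.12-fold (1.04 to 1.20), while Cyp4a10 was 1.12-fold (0.999 to 1.26) and Plin2 had 71.4 against 69.6. Other lists standing apart were bile acid synthesis and transport at 0.11, xenobiotic metabolism at 0.07, fatty acid and triglyceride synthesis at 0.09, male-biased genes at 0.11 and ribosomal proteins at 0.06, all higher. Acute phase genes at -0.07 and amino acid catabolism at -0.05 were lower. In all, 10 of 28 lists stood apart, where 1.4 are expected for lists of unrelated genes, but 3 of 28 did with unmatched random lists. These were the pericentral, periportal and cell cycle lists, and the other 8 of the 10 came inside the limits. Male-biased genes also came inside with the mean in place of the median (0.06, percentile 89.2), and ribosomal proteins when matched on RNA make-up (percentile 95.8). Lists share members, such as Sds in the periportal and amino acid catabolism lists and Cyp3a11 in the pericentral and xenobiotic lists. The 10 lists are therefore not 10 separate results. Members of a list may also vary together between any 2 libraries, so more than 1.4 lists may stand apart without an effect of the gate.

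Single genes differed little between the control gates. In the positive library 13 genes were at least 2-fold higher and 17 lower among 8973, where counting alone gave 7.49 in both directions on average and 17 at most in 100 draws. Scaling by column totals made that 15 higher and 11 lower. The largest positive differences were of low genes: Pcnxl4 at 3.45 against 0.821, Csrp3 at 6.68 against 2.26, Sort1 at 5.82 against 2.05, Far2 at 6.25 against 2.26 and Ubald2 at 7.55 against 2.87. The largest negative ones were Sox9, a biliary transcription factor, at 1.29 against 5.34, then Samd14 at 2.59 against 6.98, Tpcn2 at 3.66 against 9.03 and Nid1 at 1.94 against 5.13. With a pseudocount of 5 the counts were 2 and 1.

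Between the gates of bezafibrate mice, the positive library had lower values of several metabolic lists and of secreted proteins than the negative library. Other metabolic lists were inside the limits. They were omega-oxidation at -0.25 (percentile 2.7), amino acid catabolism at -0.14 (11.6), fatty acid and triglyceride synthesis at -0.09 (31.3), gluconeogenesis and glycogen at -0.08 (34.9) and bile acid synthesis and transport at -0.04 (52.4). The 28 secreted protein genes had a median of -0.39 (percentile 0), with 28 members below 0, among them Alb at 48208 against 72188 and Apob 0.649-fold (0.642 to 0.656). Apoe was 0.998-fold (0.988 to 1.01), and above 1 when scaled by column totals or without the 100 highest genes. The mitochondrial beta-oxidation list had a median of -0.28 (percentile 0.020), with 21 of 25 members below 0, among them Cpt2 at 39.7 against 62.8. Acsl1 had 994.7 against 1166, and Etfb went the other way at 152.4 against 125.4. The peroxisomal list had a median of -0.23 (percentile 0.25), with Abcd2 at 10.2 against 16.5 and Acaa1a higher at 125.8 against 90.8, and the respiratory chain list -0.32, with 64 of 74 members below 0. Cyp4a10, at 1048 against 1584, was 0.662-fold (0.642 to 0.682), and Ehhadh 0.699-fold. Rn45s was 174815 in the positive against 99961 in the negative library beside each of these groups, and differences ran with transcript length, with medians of -0.09 in the fifth of genes with the shortest transcripts and 0.04 in the fifth with the longest.

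Both zonation lists had medians below 0. Pericentral genes had a median of -0.19 (percentile 0.24) and periportal genes -0.21 (percentile 1.41). The latter were inside the limits with the mean in place of the median (percentile 8.29) or matched on transcript length (percentile 3.43). Glul had 111.4 against 109.8 and Cyp2f2 was 0.739-fold. The gate difference under bezafibrate minus that in control mice had a median of -0.42 for pericentral genes (percentile 0 among random lists) and -0.07 for periportal genes (percentile 48.9). Immediate early genes were the 1 list standing apart on the higher side, at 0.17 (percentile 99.8), with Jun at 751.2 against 576.4 and Gadd45g at 132.4 against 84.1. Cholesterol synthesis, citric acid cycle, ketone body synthesis, acute phase, xenobiotic, ribosomal protein, histone, sex-biased and PPARalpha target lists also stood apart on the lower side, with medians between -0.22 and -0.36. The histone median was 0.078 with a filter at 20. With the mean in place of the median, the PPARalpha target and ketone body lists came inside the limits at -0.09 and -0.15 (percentiles 13.1 and 14.3), the second also with a filter at 20 (percentile 3.50), and the female-biased list did with no filter at -0.16 (percentile 3.17). At least 2-fold differences were 12 higher and 11 lower, against 0.87 from counting alone. Among the largest, Gstp2 had 12.6 against 3.73, Ubald2 5.52 against 1.87, Necap2 7.72 against 3.07, Lars2 25.2 against 130.6, Mrpl42 5.36 against 13.3 and Eno1 70.1 against 156.2.

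Some of the largest differences belong to near-identical copies and are uncertain. Amd1 (chromosome 10, 40287458 to 40302186) had 277 reads in bezafibrate positive and 0 in the other 4 libraries. Amd2 (chromosome 10, 35708675 to 35711892) had 3 reads there and 166 to 316 in the others. Their summed normalised read count was 44.1 in bezafibrate positive and 34.1 to 44.0 elsewhere. Mup19, one of the major urinary protein genes, had 27.6 in bezafibrate negative and at most 0.158 in the other libraries.

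The high gate of bezafibrate mice had higher values of mitochondrial beta-oxidation and peroxisomal genes than the positive gate, but not than the negative gate. The mitochondrial beta-oxidation list was higher by a median of 0.11 (percentile 99.9), with 20 of 25 members above 0 and Cpt2 at 51.8 against 39.7. The peroxisomal list was higher by 0.10 (percentile 99.6), with Ehhadh at 1535 against 1268. Omega-oxidation was inside the limits at 0.05 (percentile 81.6), with 7 of 11 members above 0. Against the negative gate, the high gate had medians of -0.12 for mitochondrial beta-oxidation (percentile 3.76, 18 of 25 members below 0), -0.13 for the peroxisomal list (percentile 4.67) and -0.25 for omega-oxidation (percentile 0.89), and 12 of 28 lists stood apart on the lower side and 1 on the higher. Over the positive gate, secreted proteins were higher by 0.13, cholesterol synthesis by 0.10 and hypoxia response genes by 0.12, and the other 23 lists lay inside the limits. With filters at 1, 20 and none, 9, 8 and 10 lists stood apart, and the hypoxia list came inside with no filter (percentile 97.49) or the mean (percentile 96.1). Cyp4a10 was 1.11-fold higher than in the positive gate (1.07 to 1.14), while Cpt1a had 322.7 against 326.3, with the other sign when scaled by column totals. Rn45s was lower here, at 123019 against 174815. Genes at least 2-fold different from the positive gate were 6 higher and 7 lower, against 0.72 in both directions from counting alone and 3 at most in 100 draws, with 11 higher and 7 lower when scaled by column totals. Outside Amd1 and Amd2, Vsig10 had 6.26 against 2.21, Dnaaf2 6.93 against 2.99, and Srp54c, which has close copies, 2.93 against 12.3.

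Across the 3 bezafibrate gates, 0 genes were graded upward and 3 downward, with at least 1.5-fold at each step. They were Gm20594 at 188.8, 21.0 and 6.13, the small RNA Rprl3 at 2391, 951.3 and 585.9, and Hmgn5 at 18.4, 9.46 and 5.20, all named after their values were seen. The steps share the positive library. Their correlation across genes was -0.52 (Spearman -0.46), where unchanged libraries gave -0.54 on average, and their covariance was -0.0417 against -0.0167.

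**Figure D2:**
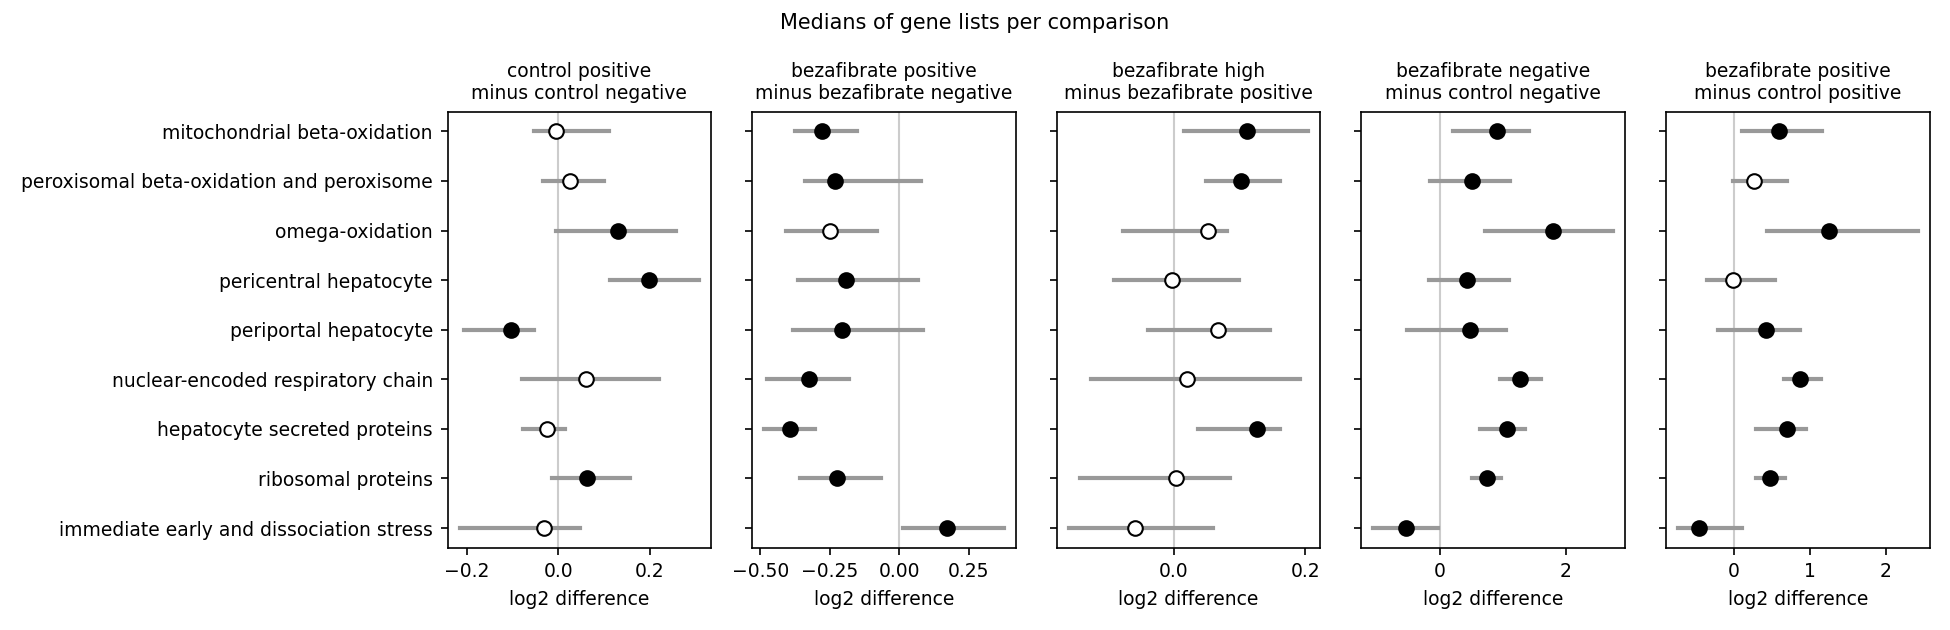
Median log2 difference (x axis, a separate scale per panel) of 9 gene lists (y axis) in the 5 comparisons. Filled points stand apart from 10000 random lists and open points do not; grey bars span the quartiles of the members. The pericentral list lies at 0.20 between the control gates and at -0.19 between the bezafibrate gates.

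Bezafibrate libraries had higher values of many fatty acid oxidation genes than control libraries in both gates. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation (chromosome 16, 21761287 to 21787807), was 24.9-fold higher in the negative gate (22.4 to 27.7) and 14.5-fold in the positive gate (13.1 to 16.0). The fatty acid omega-hydroxylase Cyp4a10 (chromosome 4, 115518264 to 115533649) was 13.5-fold (12.4 to 14.8) and 7.98-fold higher (7.35 to 8.69), and Cyp4a14 7.43-fold and 5.27-fold. Cpt1a was 1.07-fold (1.01 to 1.14) in the negative gate and had 326.3 against 325.1 in the positive gate. The kinase Pdk4 was 0.448-fold (0.269 to 0.737) and 0.444-fold (0.275 to 0.708).

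**Figure D3:**
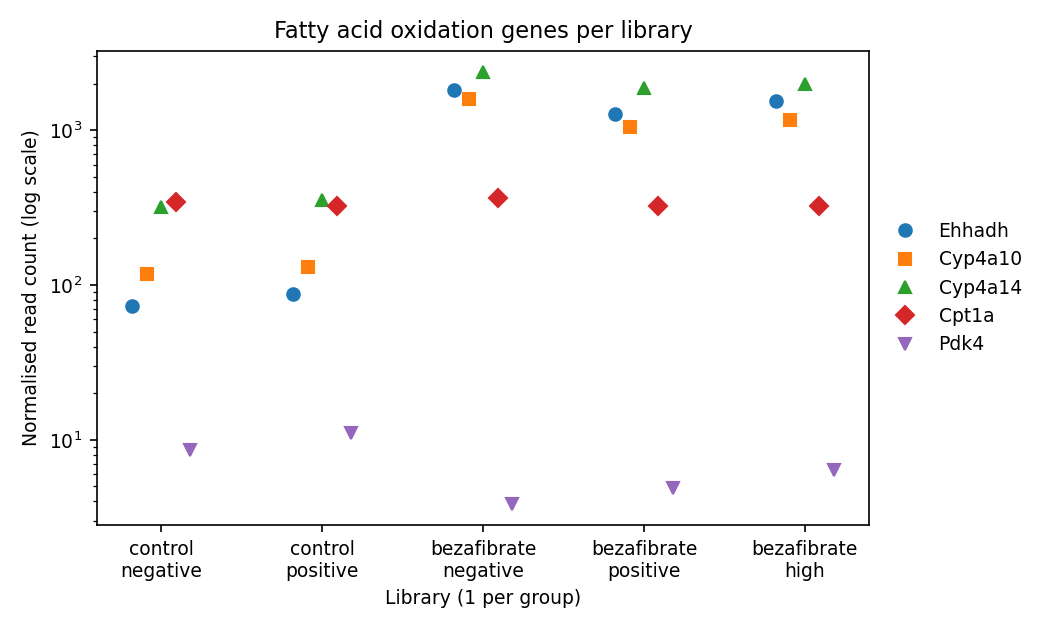
Normalised read counts (log axis) of Ehhadh, Cyp4a10, Cyp4a14, Cpt1a and the kinase Pdk4 in each of the 5 libraries. There is 1 point per gene and library, with no replicates and so no error bars. Pdk4 belongs to the list of PPARalpha target genes outside beta-oxidation. Ehhadh sits at 72.9 and 87.5 in the control libraries and between 1268 and 1813 in the bezafibrate libraries, while Cpt1a stays between 322.7 and 366.2.

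As lists, 25 mitochondrial beta-oxidation genes were higher by a median of 0.90 in the negative gate (percentile 100) and 0.59 in the positive gate (percentile 100), with 21 and 20 members above 0. Eci1 was 4.15-fold higher in the negative gate (3.27 to 5.32) and Hadhb 2.92-fold in the positive gate (2.33 to 3.70), while Acsl1, which activates fatty acids, was 0.765-fold and 0.645-fold. The 11 omega-oxidation genes were higher by 1.80 and 1.26 (both percentile 100). This list holds Cyp4a12b, which has near-identical copies, beside other Cyp4a genes, so its members may not all be separate measurements. The 29 peroxisomal genes were higher by 0.51 (percentile 98.9) and 0.26 (percentile 95.6), the second inside the limits. The first was inside them too with random lists matched on transcript length (percentile 97.4) or RNA make-up (percentile 93.8). The medians of 30 PPARalpha target genes outside beta-oxidation were not apart, at 0.24 (percentile 86.2) and 0.18 (percentile 88.7). The members were mixed, with Retsat 11.4-fold and 8.27-fold higher and Fgf21 0.255-fold and 0.379-fold. Of the 30, 9 were at least 2-fold higher and 1 lower in the negative gate, and 6 and 3 in the positive gate. Among all 8973 genes, 919 were higher and 526 lower in the negative gate, and 443 and 261 in the positive gate.

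Genes of other functions were higher as well. The 74 nuclear-encoded respiratory chain genes were higher by 1.27 and 0.87, with 72 and 73 members above 0, among them Atp5b at 2.82-fold and 1.89-fold. Secreted proteins were higher by 1.06 and 0.69, with Alb 2.97-fold and 2.09-fold higher. Apoe was 0.954-fold and 0.911-fold, and above 1 in both gates when scaled by column totals. With random lists matched on RNA make-up, secreted proteins were inside the limits in the positive gate (percentile 94.4). Ribosomal proteins were higher by 0.75 and 0.47, citric acid cycle genes by 0.99 and 0.74, acute phase genes by 0.94 and 0.65, and xenobiotic metabolism by 0.83 and 0.69, with Cyp3a11 at 3.35-fold and 2.22-fold. Ketone body synthesis genes were higher by 0.90 and 0.61, but inside the limits with the mean in place of the median (0.61 and 0.36, percentiles 93.5 and 88.3) or matched on RNA make-up (percentiles 94.6 and 97.1). They were also inside with a filter at 1 or none in the negative gate (percentiles 96.3 and 96.7) and at 20 in the positive gate (percentile 95.7). Pericentral genes were higher in the negative gate by 0.42 (percentile 98.98), and at -0.01 in the positive gate (percentile 41.9). In the negative gate they were inside the limits when matched on transcript length (percentile 95.3) or with a filter at 1 or none (percentiles 96.05 and 95.79). Periportal genes were higher by 0.48 and 0.42 (percentiles 98.0 and 99.6). They were inside the limits in the negative gate when matched on length or RNA make-up (percentiles 91.1 and 93.0) or with a filter at 20 (percentile 96.7). With the mean in place of the median they were inside in the negative gate (percentile 86.6) and in the positive gate (percentile 97.4). Interferon response genes stood apart in the negative gate, at 0.49, but not with the mean (percentile 96.1), a filter at 20 (percentile 91.4), unmatched random lists (percentile 97.3) or no filter, where the median was 0.25 (percentile 94.6). Bile acid synthesis and transport at 0.52, gluconeogenesis and glycogen at 0.42, and amino acid catabolism at 0.34 stood apart in the positive gate, the last 2 not with the mean, at 0.20 and 0.36 (percentiles 75.1 and 97.4). Gluconeogenesis genes also came inside when scaled by column totals or median of ratios, and amino acid catabolism with a filter at 20 or matched on transcript length (percentiles 96.5 and 96.0). In the negative gate the bile acid, gluconeogenesis and amino acid lists had similar medians of 0.53, 0.53 and 0.49. They were inside the limits there (percentiles 96.3, 96.1 and 96.3), but bile acid genes stood apart when matched on RNA make-up (percentile 98.9). Rn45s was lower in the bezafibrate libraries beside each of these groups, and differences also ran with transcript length. Medians were 0.26 and 0.16 in the fifth of genes with the shortest transcripts and -0.13 and -0.10 in the fifth with the longest, with Spearman correlations across genes of -0.18 and -0.16. Length-matched random lists had medians of 0.28 and 0.17 for the respiratory chain, and of 0.35 and 0.21 for ribosomal proteins, which stayed at percentiles 99.98 and 99.89 among them.

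Oxidative stress, endoplasmic reticulum stress, cell cycle and clock output lists were inside the limits in the 5 comparisons under the main settings. The clock output list holds genes of opposite phase, whose differences can cancel in a median. Matched on RNA make-up, it stood apart for bezafibrate against control in the positive gate (percentile 98.7). Immediate early genes were lower by a median of -0.54 (percentile 0.010) and -0.46 (percentile 0), with Jun 0.432-fold and 0.536-fold and Myc 0.172-fold and 0.195-fold. In the negative gate 919 genes were at least 2-fold higher and 526 lower, and in the positive gate 443 higher and 261 lower, where counting alone gave 1.73 and 2.51. Scaling by column totals, which moved the median of all genes from 0.02 to 0.25 in the negative gate and from 0.00 to 0.20 in the positive gate, gave 1444 and 267, and 820 and 131. Scaling by totals without the 100 highest genes gave 768 and 676 in the negative gate. With the high library in place of the positive one, 524 were higher and 293 lower.

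The largest single differences included genes outside fat metabolism. Rassf4 had 0.821 and 1.08 in the control against 227.9 and 309.7 in the bezafibrate libraries of the same gates, and Cwc22, a splicing factor, 17.9 and 14.9 against 267.3 and 361.7. Treatment was confounded with mouse in this outbred stock, so a difference between mice in Rassf4 and Cwc22 was not separated from one between treatments. Retsat, Aadac and Cyp4a12b were also among the 10 largest of the negative gate, with Mup15 and Mup9 from the major urinary protein genes. Cyp4a12b and the Mup genes have near-identical copies, so their values are uncertain. On the lower side, Onecut1, a hepatocyte transcription factor, had 37.3 and 27.7 in the bezafibrate against 401.8 and 384.6 in the control libraries. Col5a3 had 15.5 and 27.4 against 207.2 and 184.3, and Cyp2b13 4.13 and 2.99 against 30.6 and 31.5. Tmod1 had 0 reads in bezafibrate negative and 21.1 in control negative, 52.9-fold lower when the floor of 3 reads is put for 0. The 95% counting interval of the ratio reached 0.0237, so it allows a smaller fold than that. In the positive gate Tmod1 had 6.78 against 10.3, 0.655-fold (0.424 to 1.01). In the positive gate Dbp, a clock output transcription factor, was 11.1-fold higher (7.65 to 16.8), and Cish and Hmox1 were lower at 4.10 against 30.2 and 34.2 against 202.9.

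The gate differences of the 2 treatments showed little correlation across genes. Pearson's r was -0.02 and Spearman's rho -0.07 over 8973 genes, which are not independent replicates, and 47.9% of genes had the same sign. The control gate difference had a standard deviation of 0.257 across genes, where counting alone gave 0.216. For the bezafibrate gates, positive minus negative, it was 0.329 against 0.175. Counting error pulls such a correlation toward 0, so the low r cannot show that the gates differ in unrelated ways. Of the genes at least 2-fold different, 3 were higher and 1 lower in both, where independent lists would share 0.0174 and 0.0208, and 2 went opposite ways. The shared genes, named after their values were seen, were Ubald2, Gm14308 and Gm14430 on the higher and Gm20594 on the lower side. Gm14308 differed by 4.21 in control and 3.42 under bezafibrate, and Gm14430 by 3.89 and 5.20. Of the opposite genes, 0610010B08Rik went from -2.87 to 3.79 and Samd14 from -1.15 to 1.07. Whether reads of the provisionally named genes belong to close copies was not checked, so this overlap is uncertain. The bezafibrate differences of the 2 gates, which share no library, had r = 0.83 and rho = 0.82. Their standard deviations were 0.754 in the negative and 0.602 in the positive gate, against 0.188 and 0.198 from counting alone. Of the genes at least 2-fold different, 354 were higher and 191 lower in both gates, where independent lists would share 45.4 and 15.3, and 2 went opposite ways. The gates of a treatment may come from the same mice, so this is not replication of the bezafibrate difference.

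**Figure D4:**
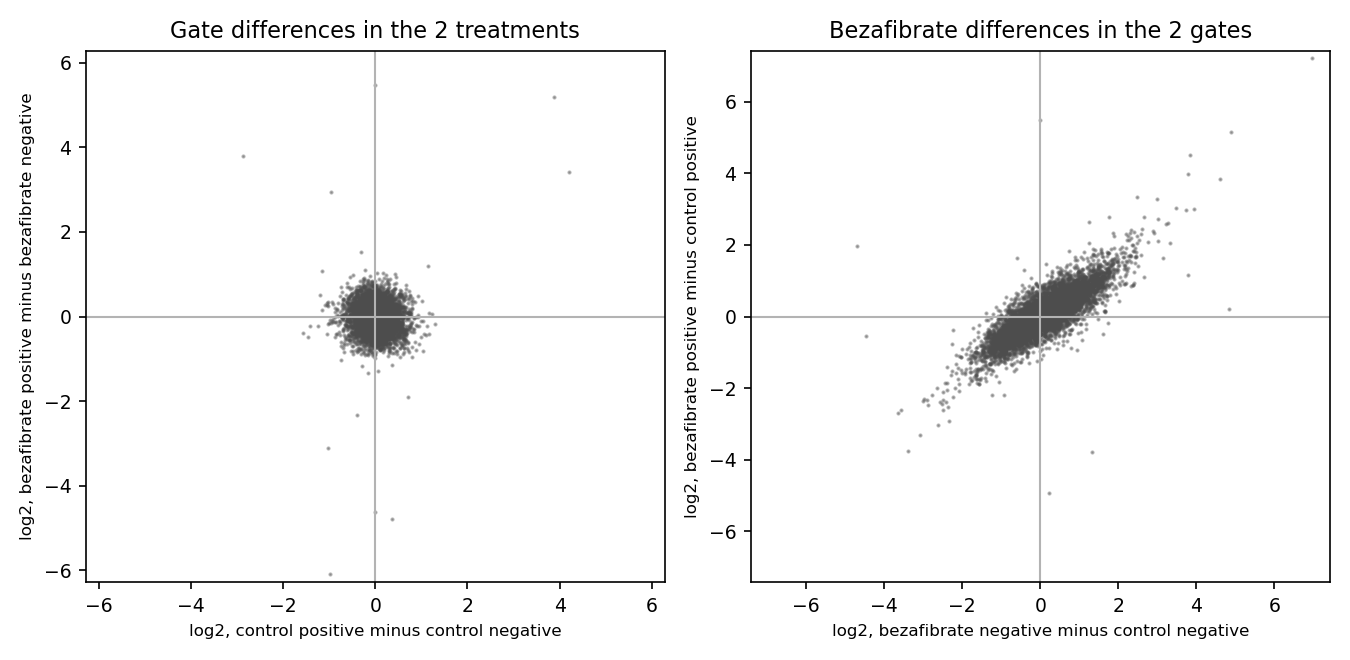
Log2 differences of 8973 genes, 1 point per gene. The left panel sets the gate difference under bezafibrate (y axis) against that in control mice (x axis), with r = -0.02, and the right panel the bezafibrate difference in the positive gate against that in the negative gate, with r = 0.83.

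As a limit beside these values, the additive limma fit over 4 libraries called 2196 genes higher and 1868 lower with bezafibrate, and 3 higher and 5 lower with the positive gate, of 310 at an unadjusted p under 0.05. The edgeR fit on the recovered reads, of which 100% were whole, called 2162 and 1944 for bezafibrate and 4 and 7 for the gate. These fits take the gate by treatment difference as error and do not measure the spread between mice.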

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

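The test of the pericentral difference under bezafibrate was chosen after the result was seen, and matching on transcript length or RNA make-up after the data were seen. The 4 lists given here stood apart in opposite directions between the gates of the 2 treatments, with 1 library per group, so the spread between mice was not measured. Rn45s held 36.3% and 34.8% of reads in control negative and positive, but 10.5% and 18.5% in bezafibrate negative and positive, and these differences were not matched on RNA make-up. For the per-gene difference between treatments, 16 of 28 lists stood apart among random lists, 15 of them lower. For lists of unrelated genes 1.4 are expected, but members of a list may vary together between any libraries. Lists also share members, such as Cyp3a11 in the pericentral and xenobiotic lists, so the 16 lists are not 16 separate results. The pericentral list had a median of 0.20 between the control gates and -0.19 between the bezafibrate gates, and the median of the per-gene difference between treatments was -0.42 (percentile 0). Xenobiotic metabolism genes were 0.07 and -0.24 (difference -0.31, percentile 0.03), male-biased liver genes 0.11 and -0.29 (difference -0.31, percentile 0.26), and ribosomal proteins 0.06 and -0.22 (difference -0.26, percentile 0). Between the control gates these 3 lists came inside the limits with unmatched random lists (percentiles 95.5, 96.95 and 97.1), male-biased genes also with the mean (89.2), and ribosomal proteins also when matched on RNA make-up (95.8).

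In the control gates the pericentral list was higher and the periportal list lower, with medians 0.30 apart. Counting error is argued against, as 95% of 1000 simulated differences lay between -0.0417 and 0.0403, and so is transcript length, since the pericentral list stayed at percentile 100 among lists matched on length. Matching on RNA make-up also left it at percentile 100. That match uses bezafibrate high minus negative, a noisy gate difference, and not the share of Rn45s, Malat1 and Neat1. It therefore cannot decide whether that share had a part. Rn45s held 36.3% and 34.8% of reads in control negative and positive. A positive gate that takes more pericentral hepatocytes was not seen under bezafibrate, where the medians were 0.01 apart (percentile 42.3), but with 1 library per gate and bezafibrate gates that also differed in RNA make-up it may still hold and stays open, as do differences between mice.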

How the results depend on the processing

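Scaling, pseudocount, filter, summary and matching were varied 1 at a time; matching on length or RNA make-up, the edgeR fit and the high library in place of the positive one were chosen after the data were seen. Of the list medians, 1831 comparisons with an alternative kept their side of the limits, 55 came inside, 39 moved outside and 1 reversed. Filters alter which low genes enter; for the other settings the cause was not tested. Depth of 5056884 to 7146578 reads limits genes near the filter.

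Counts of 2-fold genes moved by over 1.5 times with filters, pseudocounts or column totals. For control positive minus negative, 13 higher and 17 lower became 27 and 26 at a pseudocount of 0.25, 2 and 1 at 5, 64 and 86 with a filter at 1, 1 and 2 at 20, and 83 and 149 with none; column totals gave 11 lower. For bezafibrate positive minus negative, 12 higher became 19 and 6 at pseudocounts of 0.25 and 5; filters at 1, 20 and none gave 38 and 35, 2 and 6, and 44 and 48. For high minus positive, 6 higher became 11 with column totals and 12 and 3 at pseudocounts of 0.25 and 5; the filters gave 57 and 37, 2 and 2, and 85 and 48. For bezafibrate minus control in the negative gate, column totals gave 1444 higher and 267 lower, a filter at 20 gave 574 and 300, a pseudocount of 5 gave 317 lower and no filter 809 lower. In the positive gate, column totals gave 820 and 131, a pseudocount of 5 gave 273 and 138, a filter at 20 gave 273 and 132, and no filter 665 and 421.

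Graded genes were 5 at a pseudocount of 0.25, and 8 with a filter at 1 and 8 with none. The correlation of gate differences was -0.043 at a pseudocount of 5. That of bezafibrate differences was 0.82 and 0.86 at pseudocounts of 0.25 and 5, and 0.76, 0.89 and 0.71 with filters at 1, 20 and none. The limma fit called 1 gene higher for the gate and 1435 higher for treatment with a filter at 20, and 1 lower for the gate under median of ratios. Lists standing apart numbered 3 of 28 between control gates with unmatched random lists, and 9, 8 and 10 for high minus positive with filters at 1, 20 and none.

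For bezafibrate in the negative gate, the peroxisomal list (0.51) came inside the limits when matched on length (percentile 97.4) or RNA make-up (93.8), the pericentral list with a filter at 1 or none (0.32) and matched on length (0.42, percentile 95.3), and the periportal list with a filter at 20 (0.52), the mean (0.32), and matching on length or RNA make-up (0.48). In the positive gate, the peroxisomal list moved outside with a filter at 20 (0.46), the mean (0.44) and unmatched lists (0.26), and the periportal list came inside with the mean (0.33). Between control gates, omega-oxidation came inside with unmatched lists (0.13). Between bezafibrate gates, omega-oxidation moved outside with the mean (-0.24) and unmatched lists (-0.25), and the periportal list came inside with the mean (-0.12) and matched on length (-0.21). The periportal list moved outside for high minus positive with the mean (0.077). Histone genes reversed between bezafibrate gates, from -0.31 to 0.078 with a filter at 20, where fewer members remained.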

Other observations

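The test of RNA make-up as an explanation for the bezafibrate differences, and the genes named in the next paragraph, were chosen after the values were seen; so was matching on transcript length, though what its test would show was written before its result, as for the tests of the clock genes.

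Sex-biased liver genes differed between the bezafibrate and control libraries. The list higher in males was higher by 1.18 in the negative gate and 0.94 in the positive gate (both percentile 100), with Mup1 2.93-fold and 2.26-fold higher and Elovl3 at 3.94 against 13.2 in the positive gate. This list as fixed includes Mup genes and Cyp4a12b, which have near-identical copies, so its members may not all be separate measurements. It also shares members with the omega-oxidation list, such as Cyp4a12b, and with the peroxisomal list. The list higher in females was lower in the positive gate at -0.40 (percentile 0.59) and inside the limits in the negative gate at -0.26 (percentile 10.2), with Hamp2 7.88-fold and 5.28-fold higher. The cytokine signalling inhibitors Cish and Socs2 had 33.3 and 185.4 in control negative and 5.07 and 38.5 in bezafibrate negative. Rn45s held 36.3% and 34.8% of reads in the control negative and positive libraries and 10.5% and 18.5% in bezafibrate negative and positive beside these lists. With random lists matched on RNA make-up, the male list stayed at percentile 100 and 99.99, and the female list lay at 6.57 and 0.03. With no filter on low values the female list came inside the limits in the positive gate at -0.24 (percentile 2.77). Y-linked Ddx3y lay between 55.0 and 69.3 in the 5 libraries.

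Respiratory chain, ribosomal protein, secreted protein and mitochondrial beta-oxidation genes were higher in the bezafibrate libraries. Transcript length as the whole cause is argued against, for the beta-oxidation list, which stayed at percentile 99.91 or above in both gates among lists matched on length, and the ribosomal proteins, nuclear-encoded respiratory chain and hepatocyte secreted proteins lists stayed at 99.89 or above with that matching, but lists matched to ribosomal proteins had medians of 0.35 and 0.21 themselves, so a part may run with length. Among lists matched on RNA make-up, the beta-oxidation list stayed at percentile 99.94 in the positive gate, and the respiratory and ribosomal lists at 100 and 99.8. That match uses a noisy gate difference, bezafibrate high minus negative, and not the share of Rn45s, Malat1 and Neat1, so it cannot exclude that share. The secreted list came inside the limits at 94.4, and the 4 lists were lower in bezafibrate positive than negative, so a part may come from that share. An action of bezafibrate on PPARalpha target genes stays open, as its test is not reported here. When the bezafibrate high minus negative difference was scaled up by the Rn45s difference, a comparison chosen afterwards, it gave 1.06 for the respiratory chain (0.87 observed in the positive gate), 0.94 for ribosomal proteins (0.47), 1.05 for secreted proteins (0.69), 0.46 for beta-oxidation (0.59) and 0.89 for Ehhadh (3.84), while scaling by Malat1 gave 0.45, 0.40, 0.45, 0.20 and 0.38, so how large a part the RNA make-up had stays open.

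Some clock genes differed between treatments, though the clock output list, which mixes phases, was inside the limits. Dbp had 6.98 and 6.25 in the control libraries and 63.1, 69.7 and 70.1 in the bezafibrate libraries, while Arntl had 19.7 and 22.6 against 12.5, 10.1 and 10.4. A different time of day of the livers may account for this, since the medians of 7 and 5 genes of opposite phase were 0.96 and -0.61 in the negative gate and 1.06 and -0.99 in the positive gate, at least 1.58 apart. These medians were not placed among random lists. For Dbp and Ciart only, the share of Rn45s, Malat1 and Neat1 is argued against, because their gate difference was 0.0498 of their bezafibrate difference. The other phase genes were not covered by that test. An effect of bezafibrate on these genes was not tested and stays open.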
